A study of Drosophila melanogaster with 76 samples.

How the data were processed

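Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed from cultured Drosophila melanogaster S2 cells, a line with properties of embryonic blood cells, per the labels either left as wild type or carrying a construct that expresses a transcription factor after addition of copper sulfate. The factors were Zelda (Zld), Grainy head (Grh) and Twist (Twi), the last also with an HA tag (HA-Twi), and truncated Zld and Grh constructs named DBD in the labels, read here as their DNA-binding domains. Samples were grouped by the title of each library, which names the construct, the copper dose, the antibody and, in 1 set of experiments, DMSO or a treatment written "taz" in the labels.

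The series holds 76 libraries. Peak lists were analysed for the groups of 62 of them, in 31 lists, each of which the labels tie to 2 libraries of a group. No list separates the 2 libraries, so no spread between libraries and no test between groups could be computed. The other 14 libraries, inputs of wild-type cells and immunoprecipitations with IgG and their inputs, were not analysed here. The only measure of spread between experiments is the comparison of lists of the same construct, dose and antibody made under different titles, which are called repeat experiments below.

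Bowtie2 2.4.4, MACS2 2.2, deepTools 3.5.1 and the genome build dm6 are named per the submitters' processing notes, without the role or settings of each. The peak lists are the authors' narrowPeak files, deposited with several summits per region. Each gives a fold enrichment, a ratio of the immunoprecipitation to the local background at the summit as the authors' peak caller computed it, and the −log10 p-value and −log10 q-value of the summit, also deposited by the authors. The filter that led to the deposited lists is not given in the sources used here. Peak numbers in the deposited names had gaps, with 16.7% to 86.8% of the numbers kept, so part of the called peaks had been removed from each list. The highest number in the names is used as a lower bound on the peaks called before the filter; a region described as called is one in the deposited list. The fold was used only to rank, describe or filter regions within a list; folds of different lists printed side by side are not measures of relative strength. How the filter differed between lists is unknown, and region numbers depend on it.

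Rows with the same chromosome, start and end were joined to 1 region with its highest fold; the 258174 summits in all lists gave 179969 regions. In 2 rows the summit lay beyond the region's end and was moved to the region's last base. Regions of 2 lists were counted as shared when they overlapped by at least 1 bp. Where wild-type or uninduced regions were removed, both lists of a pair lost them, unless the whole second list is named. Shares are given with exact Clopper-Pearson 95% binomial intervals, which cover counting error only; neighbouring regions are not independent, and no p-value was computed across regions or genes. Beside shares stand the mean of 100 draws in which every region of the first list was shifted at random along its chromosome (20 draws for the position of summits) and, where given, the overlap of independent lists, n1 × n2 / N, within the 18718 merged regions of all lists, which cover 22.2 Mb.

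Sequencing depth is not stated in the files. The local background pileup at each summit was recovered from the deposited fold and −log10 p-value with the Poisson model of the peak caller, using summits with a −log10 p-value up to 250. In 14 of the 31 lists at least 99% of the recovered pileups were whole numbers within a relative tolerance of 0.0001; in 17 they were not, which leaves an unknown scaling. The 1st percentile of the recovered background, taken as the genome-wide level, ranged from 14.7 to 82.7 between lists. Divided by the shortest region of the list it ranged from 72.6 to 219 per kb. It describes the background behind a list and is not a count of reads.

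Gene positions came from a table of the annotation on the same assembly as dm6, with 13922 protein-coding genes. The table used here has no strand, exons or introns, and no genome sequence was used. Compared with the plan made before the data were examined, distance to a transcription start was therefore replaced by distance to either end of a gene (500 bp), the gene-list window became the gene span with 2000 bp to both sides, the nearest gene was taken by distance to its span (the shortest gene where several held the summit), exons and introns were not separated, and the motif counts were not made.

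Gene lists were fixed before the data were examined: early zygotic patterning genes (known Zelda targets), epithelial and septate junction genes (known or proposed Grainy head targets), mesoderm genes (known Twist targets), blood cell genes as markers of the host cell, ribosomal protein genes, Polycomb target developmental regulators, neural genes, germline genes, copper and stress response genes, and the loci of the expressed factors with MtnA. Of 199 names, 194 matched by symbol and 4 by an older name; 1, nos, was not matched. For each list the number of genes with a summit in the window was set beside 10000 random lists of protein-coding genes of the same size, matched on window length; the percentile describes these peak lists and is not a p-value. Some genes stand on more than 1 list.

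The rule for named genes was also fixed in advance. For each factor's single-dose list it took the nearest gene of the 10 regions of highest fold that overlapped no region of the matched wild-type list. For the dose series it took 5 regions found at all induced doses and not at 0 µM, and 5 found only at the highest dose. For the DNA-binding domains it took 5 full-length regions with and 5 without a region of the truncated construct. For taz it took 5 regions in the taz list only and 5 in the DMSO list only. Of each gene list it named, in list order, up to 6 genes with a summit and up to 3 without. The expressed factors' loci and MtnA were always examined. Regions that recurred at those loci were compared by their edges, a feature chosen after its values were seen.

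The comparisons were wild-type background, overlap between factors, dose, truncated against full-length construct, taz against DMSO, and repeat experiments, with the position of summits and the gene lists as description. Alternatives chosen before the data were examined were a reciprocal overlap of at least 50%, a −log10 q-value of at least 10 in every list, the 1000 regions of highest fold, removal of regions found in the wild-type list, the list of the repeat experiment, a distance of 1000 bp to a gene end, and a gene window of 500 bp around either gene end. Added after the data were seen were the use of all 4 wild-type lists together, removal of regions found in the wild-type or the uninduced list, and thinning of the DMSO list to the depth of the taz list.

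Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9. The overlap code was tested on simulated data: a list with 39.4% of the 8354 single-dose Grh regions planted in it gave back 39.4%. The background recovery was tested on simulated summits and missed the planted 1st percentile by 0.0% with whole pileups and by -2.53% with scaled pileups.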

Results

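Binding of 3 Drosophila transcription factors was mapped by ChIP-seq in S2 cells that carried a copper-inducible construct. Zld is a zinc-finger factor that activates the first zygotic genes of the embryo, Grh is a regulator of epithelial genes, and Twi is a basic helix-loop-helix factor of the mesoderm. The data comprised 31 peak lists, each from 2 libraries. The single-dose lists held 6451 regions for Zld (1000 µM copper sulfate), 8354 for Grh (100 µM) and 12106 for Twi (40 µM). Wild-type cells given the matched copper dose had 5945 regions with the anti-Zld, 1946 with the anti-Grh, 3260 with the anti-Twi and 2264 with the anti-HA antibody. Further lists covered doses from 0 µM upward, the DNA-binding domains of Zld and Grh, and DMSO or taz. Each list pools its 2 libraries, so intervals give counting error only and the spread between experiments is taken from repeat experiments. The recovered background was 193 per kb in the Zld, 219 in the Grh and 161 in the Twi list. In the Grh list only 8.3% of the recovered pileups were whole numbers. Its value carries an unknown scaling and is not comparable with the other 2.

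The question of the first comparison was which regions depended on the expressed factor rather than on the antibody or the cell. Outside the wild-type list, the strongest Zld region lay on chromosome 3L at 11380034 to 11383241, 13374 bp from CG11726, with an authors' fold of 25.8. It was followed by a region at zld itself (fold 22.8), where construct DNA may contribute, as described below. Another lay 7524 bp from the cell-death gene hid (3L, 18191933 to 18195690, fold 22.6). Then came regions inside the BMP receptor gene tkv (2L, 5253438 to 5254993, fold 21.0) and inside sbb, which encodes a transcriptional regulator (fold 20.4). The next were near nkd, an antagonist of Wingless signalling (1401 bp away, fold 18.3), the homeobox gene scro (238 bp, fold 17.5), within T48, a gene of mesoderm invagination (3R, 26882690 to 26885395, fold 15.8), and near CG4218 (fold 15.0) and CG7320 (fold 14.5).

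The strongest Grh regions outside the wild-type anti-Grh list were at Dll, the regulator of distal limbs (2R, 24813537 to 24815422, 174 bp from the gene, fold 141), C15 (3R, 21498878 to 21500390, 343 bp, fold 113), gsb (2R, 25061127 to 25063570, 120 bp, fold 96.9) and tup (2L, 18880765 to 18882128, 272 bp, fold 84.0). Regions near vg, the wing selector gene (5140 bp, fold 83.5), the POU gene vvl (155 bp, fold 79.5), the Hox gene pb (48 bp, fold 78.8), the head gap gene ems (157 bp, fold 76.9), within tey (fold 76.6) and near the Pax gene eyg (162 bp, fold 74.1) completed the 10. Each of these regions was called in 16 to 24 of the 31 lists. In the Twi list the leading regions lay mostly within genes: prage (X, 1846315 to 1850418, fold 11.5), SP1173 (fold 11.4), the Wnt receptor gene fz (3L, 14351925 to 14355213, fold 11.3), the RNA-binding protein gene Rbfox1 (fold 11.3) and Cph (fold 11.1). Doc2, a T-box gene of the heart and dorsal ectoderm (1017 bp away, fold 11.1), CG43658 (fold 11.1), ltl (3L, 7521728 to 7523002, fold 11), the small heat-shock gene CG14207 (fold 11) and the myosin gene Myo28B1 (fold 10.9) followed. The HA-Twi list at 40 µM was led by zld (fold 10.6), ltl (fold 10.3), CG43658 (fold 10.3), sowah (fold 9.9), Slc45-1 and Rbfox1 (both fold 9.87). A further CG43658 region (fold 9.81), the gap junction gene Inx2 (fold 9.73), kirre, a gene of muscle founder cells (fold 9.61), and the adenylyl cyclase gene rut (fold 9.51) came next. Of these Twi regions, prage, SP1173, fz and CG14207 were called in 11 to 13 of the 31 lists and the others in 5 or 6. Of the HA-Twi regions, Inx2 was called in 22 lists, kirre in 21, zld in 16 and rut in 14, and the others in 6 or 7.

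Of the Zld regions, 67.4% (95% interval 66.2 to 68.5) overlapped a wild-type region, against 7.54% after random shifts. This share differed between Zld experiments at the same dose: it was 61.6% in the dose series and 25.4% (23.6 to 27.3) in the list with DMSO. The share was 16.7% (15.9 to 17.5) for Grh, 22.2% (21.5 to 22.9) for Twi and 19.2% (17.9 to 20.4) for HA-Twi at 40 µM, against 3.2%, 3.52% and 2.08% after random shifts. Among the 1000 regions of highest fold it was lower for Zld (46.6%), Twi (7.6%) and HA-Twi (9.2%) and higher for Grh (19.7%). The Grh share, and which Grh regions lay outside wild type, rest on a wild-type list with an extreme region at Mef2 (fold 386, list median 3.53) and 19.8% of its peak numbers kept. Whether that list is correctly labelled is not known. The wild-type lists overlapped each other, and 629 merged regions stood in all 4. Of the anti-HA regions 95% lay in the anti-Zld list, of the anti-Twi regions 91.8% and of the anti-Grh regions 81.9% (7.47% after random shifts). In this respect the doubted anti-Grh list resembled the other wild-type lists. Against all 4 wild-type lists at once, an alternative added after the data were seen, the shares for Grh, Twi and HA-Twi were 58.0%, 46.1% and 54.2%.

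**Figure D1:**
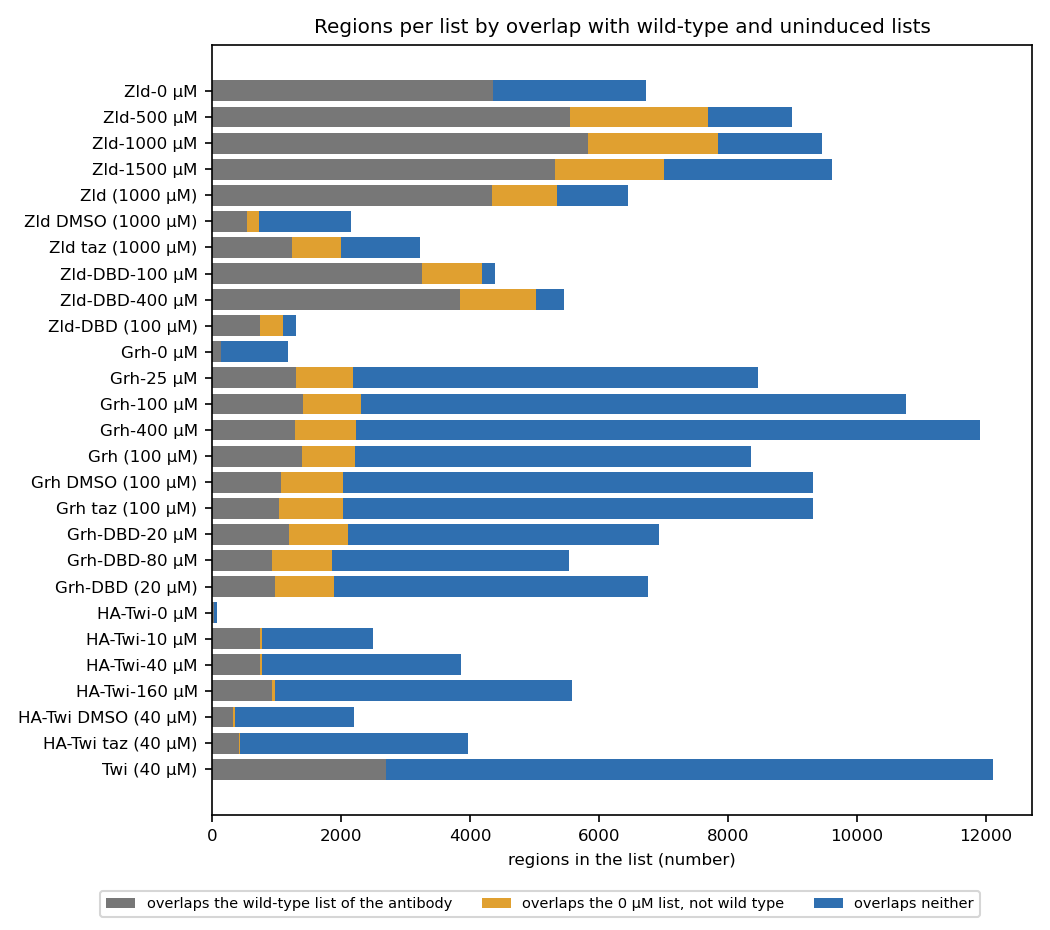
Number of regions per list (horizontal axis) for each construct and copper dose (rows), divided into regions that overlap the wild-type list of the same antibody (grey), regions that overlap the 0 µM list but not wild type (orange) and regions that overlap neither (blue). For lists at 0 µM and for Twi no 0 µM share is drawn; of the 6451 regions of the single-dose Zld list 1105 overlap neither, of the 8354 of Grh 6138.

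Genes known as targets of each factor were examined with the fixed gene lists. Grh regions lay at all 30 Polycomb target developmental regulators (random median 23) and at 27 of 29 epithelial and septate junction genes (random median 21, percentile 99.7). Examples were the Hox genes lab (fold 38.2), pb (78.8), Dfd (66.4), Scr (15.0), Antp (7.04) and Ubx (11.3), and, among epithelial genes, cora, a septate junction component (fold 16.9), shg, which encodes E-cadherin (6.49), Fas3 (6.62), sinu (4.2), the chitin synthase gene kkv (10.0) and Ddc, a cuticle-hardening enzyme and classical Grh target (21.9). The epithelial genes ple and bou had no summit. The wild-type anti-Grh list reached 17 of the 30 Polycomb targets and 6 of the 29 epithelial genes, but the wild-type anti-Zld list also reached all 30 Polycomb targets. Of the epithelial examples, cora (fold 12.1), shg (4.45) and kkv (2.22) had a summit in that anti-Zld list, and Fas3, sinu and Ddc had none. Outside the wild-type and uninduced lists, a setting added after the data were seen, Grh summits remained at 26 of the 29 epithelial genes (random median 17, percentile 100.0) and 25 of the 30 Polycomb targets (20, percentile 97.4).

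Early zygotic patterning genes had a Zld summit in 16 of 31 cases over all regions of the single-dose list (random median 19, percentile 15.9). Outside the wild-type and uninduced lists, the setting added after the data were seen, 11 of 31 had one (random median 3, percentile 100.0). In the same setting the Zld lists at 500, 1000 and 1500 µM gave 3, 7 and 13 of 31 (random medians 4, 5 and 8), and the list at 1000 µM with DMSO 13 (3). Over all regions those with a summit included twi (fold 2.8), the pair-rule genes eve (3.62) and hry, the gene hairy (7.26), the gap gene Kr (5.56), Sxl (2.31) and sog (2.42), while sc, sna and ftz had none. All 13 germline genes and 84 of 92 ribosomal protein genes had one (random medians 9 and 42), as did 26 of the 30 Polycomb targets (random median 21). Without regions of the wild-type and uninduced lists, the Zld shares fell from 91.3% to 7.61% for ribosomal protein genes, from 100.0% to 15.4% for germline genes and from 86.7% to 30.0% for Polycomb targets, and from 51.6% to 35.5% for early zygotic genes.

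Of the mesoderm genes, 24 of 30 had a Twi summit, the number also found at random (24, percentile 56.3), and 18 of 30 an HA-Twi summit at 40 µM, against 9 at random (percentile 100.0). In the HA-Twi list these were twi (fold 2.82, at a region also called in wild type with anti-HA), the muscle regulators Mef2 (5.52), tin (2.51), how (5.13) and zfh1 (3.61), and htl, which encodes the FGF receptor of the mesoderm (9.11). Of these, Mef2, tin, how and zfh1 also had a summit in wild type with anti-HA, as did 14 of the 30 mesoderm genes (random median 10, percentile 94.9). The genes sna, stumps and NetA had none in the HA-Twi list at 40 µM of the dose series. In the other HA-Twi lists at that dose, stumps had a summit with DMSO (fold 4.76) and taz (5.35) and NetA with taz (4.11). Mesoderm genes with an HA-Twi summit outside the wild-type and uninduced lists numbered 16 of 30 (random median 8, percentile 99.9). In the Twi list Mef2 (fold 9.99), tin (3.35), how (8.44), htl (8.72), stumps (7.79) and twi (3.32) had summits, and sna, CadN and Ilp4 did not. HA-Twi summits were also found at 23 of 30 Polycomb targets (random median 12) and 11 of 22 blood cell genes (random median 6, percentile 99.2). In wild type with anti-HA these counts were 12 (random median 12) and 11 (random median 7, percentile 97.7). HA-Twi summits outside the wild-type and uninduced lists remained at 20 Polycomb targets (random median 11) and 11 blood cell genes (5).

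The remaining lists gave these counts. Blood cell genes with a summit numbered 13 of 22 in the Zld, 14 in the Grh and 17 in the Twi list (random medians 14, 16 and 17). Neural genes were fewer than at random in all of these lists, with 7 of 18 for Zld, 9 for Grh, 8 for Twi and 3 for HA-Twi at 40 µM (random medians 12, 13, 14 and 5). Ribosomal protein genes numbered 80 of 92 for Grh, 85 for Twi and 7 for HA-Twi (random medians 50, 55 and 7). In wild-type cells they numbered 73 with the anti-HA antibody (random median 13) and 86 with anti-Zld (39). Copper and stress response genes had a summit in 11 of 20 cases for Zld, 15 for Grh, 17 for Twi and 6 for HA-Twi (random medians 10, 11, 12 and 2), and in 13 of 20 in the wild-type anti-HA list (3). Germline genes numbered 9 of 13 for Grh, 13 for Twi and 1 for HA-Twi. Epithelial genes numbered 17 of 29 for Zld, 24 for Twi and 8 for HA-Twi (random medians 19, 23 and 9). Early zygotic genes numbered 15 of 31 for both Grh and Twi (random medians 21 and 23) and 8 for HA-Twi (6). Mesoderm genes numbered 19 of 30 for Zld and 21 for Grh (random medians 20 and 22), and all 30 Polycomb targets had a Twi summit (25).

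**Figure D2:**
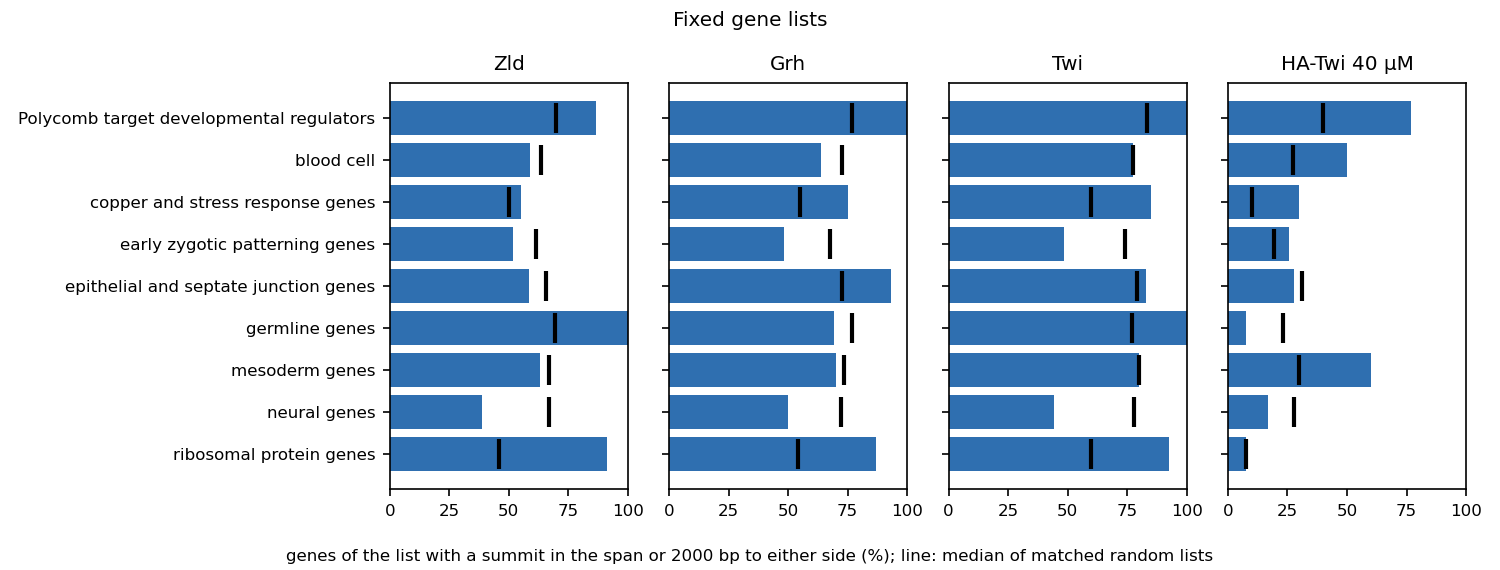
Share of the genes of each fixed list (rows) that have a summit in the gene span or within 2000 bp to either side (horizontal axis, percent) in the single-dose Zld, Grh and Twi lists and the HA-Twi list at 40 µM. Blue bars give the share and black lines the median of 10000 random lists matched on window length; for HA-Twi the mesoderm genes stand at 60.0% with a random median of 30.0%.

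The expressed factors' own loci held regions whose edges varied little between lists of the same line. At zld (X, 19766465 to 19783548) all 7 lists of the full-length Zld lines held a region of about the same extent, 5049 bp at the median edges (19777372 to 19782420), and the 3 lists of the Zld DNA-binding domain held a shorter region of 1440 bp (19777658 to 19779097). At twi (2R, 22985374 to 23048325) the 7 lists of Twi and HA-Twi lines shared a region of 1774 bp (23046409 to 23048182), which was also called in wild type with anti-HA (1641 bp) and anti-Twi (2027 bp). At grh (2R, 17801132 to 17842820) the 7 full-length lists shared a region of 1345 bp (17808374 to 17809718), and the 3 lists of the Grh DNA-binding domain one of 1005 bp (17838924 to 17839928). The latter was also called in wild type with anti-Twi (edges within 50 bp, fold 2.83) and anti-HA (within 116 bp, fold 2.02) and in the 4 full-length Grh dose lists. The strongest single-dose Grh region there lay at 17806160 to 17807877 (fold 18.6). At MtnA, the metallothionein gene (3R, 9783407 to 9784370), all 4 wild-type lists held a region, with folds of 3.02 (anti-Grh), 3.88 (anti-HA), 3.49 (anti-Twi) and 11.3 (anti-Zld). These edges were examined after their values were seen. The zld region was longer in the full-length than in the domain lists, and it led the Zld list at 0 µM (fold 10.3). DNA of the zld construct may thus contribute to it in the Zld lists, which was not tested.

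**Figure D3:**
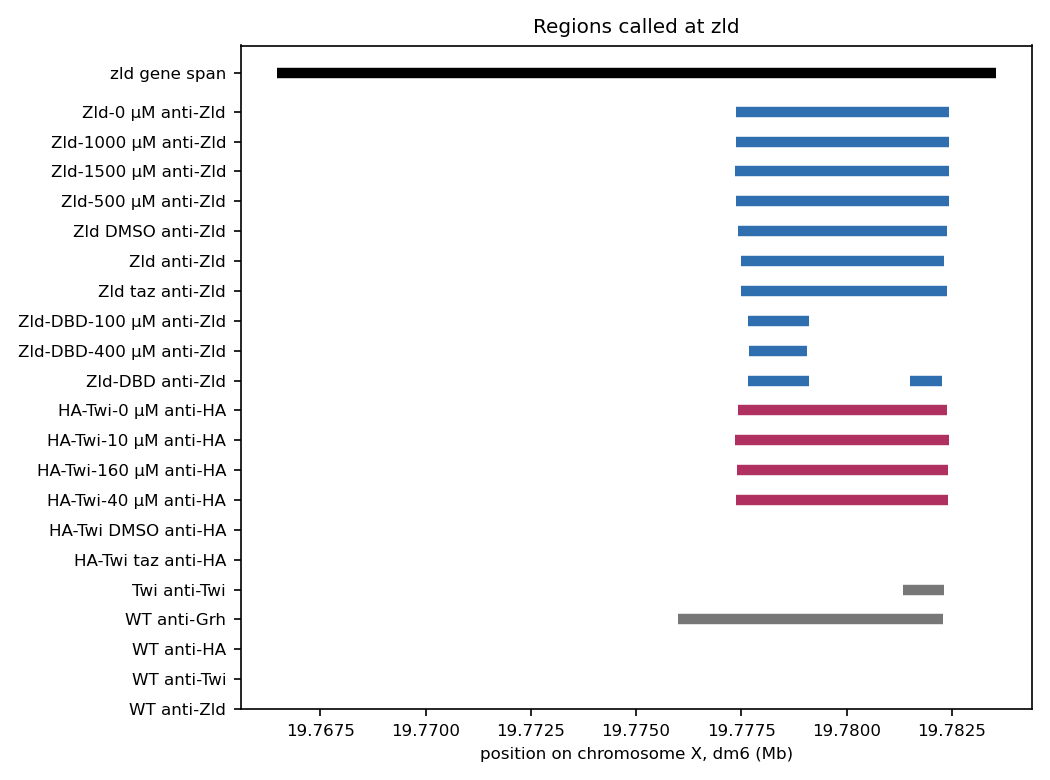
Regions called at zld on chromosome X (position in Mb, dm6; the black bar is the gene span) in the lists of the Zld lines (blue), HA-Twi lines (red), Twi and wild-type cells (grey). The region of the full-length Zld lists recurs in the 4 HA-Twi dose lists, with edges at most 39 bp from the median edges of the Zld lists. It does not recur in the HA-Twi DMSO, HA-Twi taz or wild-type anti-HA lists.

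Overlap between the factors asked how far they occupied the same regions. Of the leading Zld regions, that within T48 was called in 26 of the 31 lists, those near nkd in 19, within sbb in 18 and near hid in 17, and that within tkv in 5. Of the single-dose Zld regions, 78.5% (77.4 to 79.5) overlapped a Grh region and 82.0% (81.0 to 82.9) a Twi region. Of the Grh regions, 73.5% (72.5 to 74.5) overlapped a Twi region. Random shifts gave 13.7%, 15.2% and 18.8%. Within the merged regions, 4461 held both Zld and Grh against 2496 for independent lists, 4764 both Zld and Twi against 3317, and 6005 both Grh and Twi against 4695. Regions of the matched wild-type lists were then taken out of both lists of a pair. The shares became 47.9% for Zld in Grh, 52.8% for Zld in Twi and 51.2% for Grh in Twi. Without regions of the uninduced lists as well, they were 31.4%, 40.0% and 51.2%. The regions of the first list left in this last setting lay in the whole second list in 38.0%, 41.6% and 66.4% of cases. In the strongest 10% of Zld regions 56.6% lay in the Grh list, and in the weakest 10% 83.6%, while 80.0% of the strongest and 58.7% of the weakest 10% of Grh regions lay in the Twi list. Of the HA-Twi regions at 40 µM, 92.3% (91.5 to 93.2) lay in the Twi list. With wild-type regions taken out of both lists the share was 62.2%. Of the HA-Twi regions outside the wild-type and uninduced lists, 91.6% lay in the whole Twi list, so the lower share came from trimming the Twi list. Of the Twi regions 24.6% (23.8 to 25.3) lay in that HA-Twi list.

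The position of summits differed between lists. Of Zld summits 56.1% (54.9 to 57.3) lay within 500 bp of a gene end, of Grh summits 47.6% (46.5 to 48.7), of Twi summits 38.6% (37.7 to 39.5) and of HA-Twi summits at 40 µM 13.1% (12.1 to 14.2), where random shifts gave 15.2%, 15.3%, 15.1% and 15.1%. Wild-type summits lay there in 57.2% of cases with anti-Zld, 62.4% with anti-Grh, 50.8% with anti-Twi and 56.6% with anti-HA. Zld regions in neither the wild-type nor the uninduced list had 20.8% (18.5 to 23.3) of summits near a gene end, 50.7% elsewhere inside a gene and 28.5% outside genes. These shares differed between Zld experiments at 1000 µM: over all regions 51.7% of summits lay near a gene end in the dose series and 11.6% with DMSO, and outside the wild-type and uninduced lists 31.6% (29.3 to 33.9) and 7.97% (6.6 to 9.5).

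The dose series asked how the number and identity of regions changed with copper. Zld regions found at 500, 1000 and 1500 µM and not at 0 µM were led by those near nkd (fold 9.48 at 1500 µM), CG7320 (9.4), CG11726 (9.01), CG4218 (8.85) and hid (8.55). Found at 1500 µM and not at the lower doses of the series were regions within Srg3 (3L, 9445331 to 9446400, fold 6.37), near the pair-rule gene odd (7144 bp, fold 6.16), plh (5.92), Brd, a gene of the Notch pathway (273 bp, fold 5.89), and CG17571 (5.78). Grh regions at all induced doses were led by sano (2R, 18901287 to 18903926, fold 12.7 at 400 µM), CG6168 (12.6), the BMP-binding protein gene cv-2 (12.6), CG10283 and Mnr (both 12.5). Regions within Taf1, which encodes a subunit of the general factor TFIID (fold 9.05), CG11030 (8.94) and qm (8.84), near the citrate transporter gene Indy (8.84), and within nAChRalpha5, a nicotinic receptor subunit gene (8.8), were called at 400 µM and not at the lower doses. For HA-Twi the regions at all induced doses were led by CG43658 (X, 17503804 to 17505250, fold 10.8 at 160 µM), ltl (10.7), Rbfox1 (10.6), cv-c (10.6) and Inx2 (10.6), and those at 160 µM and not at the lower doses by Pvf2, a growth factor gene of the blood lineage (fold 6.53), Chsy (6.42), CG1907 (6.3), AdamTS-A (6.19) and bbg (6.16). Several of the regions at all induced doses were called in many of the 31 lists, with Inx2 in 22, cv-2 in 19 and CG7320 in 14. Of those at the highest dose only, Srg3 was called in 21, plh and CG17571 in 10, qm in 23, Chsy in 15 and bbg in 16. Pvf2, CG1907 and AdamTS-A were called in 4, Taf1, Indy and nAChRalpha5 in 3 and CG11030 in 1.

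Region numbers in the deposited lists rose with dose for each factor in this series. They were 6719, 8988, 9449 and 9615 for Zld at 0, 500, 1000 and 1500 µM, 1181, 8458, 10758 and 11903 for Grh at 0, 25, 100 and 400 µM, and 77, 2498, 3862 and 5581 for HA-Twi at 0, 10, 40 and 160 µM. The highest over the lowest induced dose gave a ratio of 1.07 for Zld across a dose ratio of 3, 1.41 for Grh and 2.23 for HA-Twi across a dose ratio of 16. Outside the wild-type and uninduced lists the ratio was 2.01 for Zld, 1.54 for Grh and 2.68 for HA-Twi. Repeat experiments at a fixed dose differed in number by 4.39-fold for Zld, set by the DMSO list (1.46-fold without it), by 1.29-fold for Grh and by 1.76-fold for HA-Twi, where the DMSO list is the sole repeat. Over all regions the Grh and HA-Twi ratios were larger than these differences and the Zld ratio was smaller. Outside the wild-type and uninduced lists repeats differed by 1.45-fold for Zld, 1.38-fold for Grh and 1.67-fold for HA-Twi, less than each dose ratio there. The rise for HA-Twi over the induced doses was not seen in the peak numbers: the highest peak number in the names, a lower bound on the peaks called before it, was 11152, 6963 and 8832 at 10, 40 and 160 µM, of which 22.4%, 55.5% and 63.2% were kept. The recovered background rose from 103 to 178 per kb. The ratio of these peak numbers, highest over lowest induced dose, was 0.792 for HA-Twi, 1.09 for Zld and 1.51 for Grh. Of the regions at the lowest induced dose, 80.9% (80.1 to 81.7) for Zld, 79.4% (78.5 to 80.2) for Grh and 92.8% (91.7 to 93.8) for HA-Twi were called at the highest. The share of Grh summits within 500 bp of a gene end was 46.2% (45.2 to 47.3) at 25 µM, 40.1% (39.1 to 41.0) at 100 µM and 31% (30.1 to 31.8) at 400 µM, although 2 other lists at 100 µM gave 47.6% and 36.1%.

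The uninduced lists held regions that were strong after induction. Of the strongest 10% of Zld regions at 500 µM, 91.6% were called at 0 µM and 22.7% in wild type; of the weakest 10%, 41.9% and 97.6%. Of the strongest 10% of Grh regions at 25 µM, 59.1% were called at 0 µM and 6.15% in wild type; of the weakest 10%, 0.827% and 40.1%. Against all 4 wild-type lists at once, 32.7% of the strongest 10% of Zld and 59.2% of the strongest 10% of Grh regions lay in wild type. Of all Grh regions at 0 µM 75.8% did, against 11.5% in the matched list. The Grh list at 0 µM had summits at 14 of the 30 Polycomb targets (random median 7) and 9 of the 29 epithelial genes (4). At 0 µM, HA-Twi had 77 regions, of which zld was the strongest (fold 11.7).

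The DNA-binding domains were compared with the full-length factors to ask how far the domain alone found the same regions; doses differed (Zld-DBD 100 and 400 µM against Zld 1000 µM, Grh-DBD 20 and 80 µM against Grh 100 µM). Grh regions at Dll, C15, gsb, tup and vg were also called with the Grh domain. The strongest Grh regions without one were near CG32462 (3L, 22850848 to 22852702, fold 51.9), within fred (fold 43.8), near the retinal homeobox gene Rx (2454 bp, fold 41.0), within shep (fold 40.8) and within the sex determination gene dsx (3R, 7936531 to 7937542, fold 37.4). Zld regions near hng3 (fold 25.2), at zld, near hid, within sbb and within chn (fold 18.4) were also called with the Zld domain. Those near hng3 and within chn overlapped regions of the wild-type anti-Zld list. Of all lists, 23 held the hng3 region and 28 the chn region. Their call with the domain therefore need not depend on the expressed construct. At zld the domain's region was shorter (1440 bp against 5049 bp at the median edges), so construct DNA may account for that match. The Zld regions near CG11726, within tkv, near nkd, near CG7320 and within Samuel (fold 14.5) were not called with the domain.

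Of the single-dose Zld regions, 13.9% (13.1 to 14.8) overlapped the single-dose list of the Zld domain, 44.2% (43.0 to 45.4) its list at 100 µM in the dose experiment and 52.5% (51.2 to 53.7) that at 400 µM. The single-dose list of the domain held 1302 regions and the repeat at the same dose 4391, a 3.37-fold difference, with 17.9% and 47.1% of peak numbers kept, so the share depends on the experiment. Regions of the Zld domain in neither the wild-type nor the uninduced Zld list numbered 212, 202 and 442. Of Zld regions outside those lists, 8.33%, 6.43% and 10.8% were called with the domain. With the domain lists trimmed in the same way the shares were 7.87%, 6.43% and 10.7%. For Grh, 56.3% (55.2 to 57.4) of regions overlapped the single-dose list of its domain, 60.3% (59.2 to 61.3) the 20 µM and 48.2% (47.1 to 49.2) the 80 µM list. These lists held 6763, 6928 and 5535 regions, 84.5%, 90.5% and 92.9% of which lay in the Grh list. In the strongest 10% of Grh regions 86.1% overlapped the single-dose list of the domain, in the weakest 18.9%. Random shifts gave 1.54%, 4.43% and 5.02% for the Zld lists of the domain and 10.2%, 10.3% and 7.63% for those of Grh, in the same order.

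The labels do not expand taz, and its comparison with DMSO is described as such. HA-Twi regions in the taz list only were led by X11L (X, 17602329 to 17602875, fold 8.73), Liprin-gamma (7.3), the elongation factor gene Eaf (7.09), ND-20L (7635 bp away, 7.09) and the polarity gene scrib (6.93), and those in the DMSO list only by Cph (fold 7.68), the glypican gene dally (4.28), CG7987 (3.9), the phosphodiesterase gene dnc (3.89) and IP3K2 (3.74). For Zld, regions in the taz list only lay near CG31998 (4, 205669 to 206533, fold 8.61), CG10417 (8.55), CG33217 (8.53), the mitochondrial fission gene Fis1 (8.49) and within d4 (8.45). Zld regions in the DMSO list only lay at Hsp70Bc, a heat-shock gene (fold 9.19), bcd, the anterior determinant (231 bp, fold 8.07), gsb-n (7.19), Ptpmeg2 (6.74) and mtd (6.54). For Grh they were weak: betaTub60D (fold 4.49, rank 2166 of its list), CG33144 (4.1), CG2145 (3.62), Pgant9 (3.56) and CG33181 (3.53) with taz, and nAChRalpha3 (4.87, rank 2469), kirre (4.71), CG7378 (4.71), tup (4.66) and the GATA gene grn (4.65) with DMSO. These regions are specific to a list only within their own comparison: CG31998 and CG10417 were called in 17 of the 31 lists, CG33217 in 15, d4 in 12 and Fis1 in 10, Ptpmeg2 and IP3K2 in 22, dnc in 14 and CG7378 in 13. X11L was called in 6, bcd, gsb-n, Eaf and ND-20L in 3 and Liprin-gamma in 2.

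Polycomb targets with an HA-Twi summit numbered 11 of 30 with DMSO (random median 10, percentile 71.8) and 22 with taz (random median 14, percentile 99.9), but 23 in the HA-Twi list at 40 µM without either. With taz they included pb (fold 6.53), Dfd (2.39), Scr (2.79), Antp (6.31), Ubx (4.43) and abd-A (3.26), and not lab, ey or Dll; with DMSO pb (3.04), Antp (5.82), Ubx (2.38), en (2.04), inv (7.94) and salr (4.65), and not lab, Dfd or Scr. Mesoderm genes numbered 13 of 30 with DMSO and 18 with taz (random medians 7 and 10). For Zld, early zygotic genes with a summit numbered 15 of 31 with DMSO (random median 4, percentile 100.0) and 9 with taz (random median 9, percentile 47.4). Outside the wild-type and uninduced lists they numbered 13 (random median 3) and 5 (2). With DMSO they included twi (fold 3.99), eve (5.01), hry (4.42), gt (3.1), Kr (2.74) and sog (4.68), and with taz eve (2.95), hry (3.52), sog (3.93), dpp (3.0), tld (4.07) and Sry-alpha (2.68). Grh summits were at all 30 Polycomb targets in both lists.

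In numbers, HA-Twi had 2197 regions with DMSO and 3968 with taz (ratio 1.81), Zld 2150 and 3222 (1.5) and Grh 9320 and 9317 (1.0). With a −log10 q of at least 10 in every list the ratios were 1.56 for HA-Twi, 0.924 for Zld and 0.693 for Grh. Of the DMSO regions, 91.3% (90.0 to 92.5) of HA-Twi, 52.7% (50.6 to 54.9) of Zld and 86.9% (86.2 to 87.6) of Grh were called with taz, and of the taz regions 53.4%, 37.1% and 91.8% were called with DMSO. Outside the matched wild-type list the ratio was 1.24 for Zld and 1.9 for HA-Twi. In alternatives added after the data were seen it was 1.16 and 1.98 outside all 4 wild-type lists, and 0.868 and 1.91 outside the wild-type and uninduced lists. Zld summits within 500 bp of a gene end made up 11.6% (10.3 to 13.0) with DMSO and 42.4% (40.7 to 44.2) with taz, but 7.97% (6.6 to 9.5) and 8.29% (6.8 to 10.0) outside the wild-type and uninduced lists. The highest peak number in the names was 5851 with DMSO and 3919 with taz for Zld, and 5515 and 5762 for HA-Twi. Of these numbers 36.7% and 82.2% were kept for Zld, and 39.8% and 68.9% for HA-Twi. The ratios of these peak numbers, taz over DMSO, were 0.67 and 1.04. The differences between repeats offer no independent measure here, since the 4.39-fold of Zld and the 1.76-fold of HA-Twi both involve the DMSO list. Without it the Zld repeats differed by 1.46-fold, near the ratio of 1.5, and HA-Twi had no repeat.

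Repeat experiments set the scale of these differences. Regions at Dll, gsb and C15 led the single-dose Grh list, and 94.2% (93.7 to 94.7) of its regions were called in the Grh list at 100 µM of the dose series. Over 9 pairs of lists of the same construct and dose, with the DMSO lists counted as repeats, the share of the smaller list called in the larger ranged from 55.2% to 95.7% with a median of 79.1%. The Zld list with DMSO was the lowest, with 55.2% (53.1 to 57.3) in the Zld list at 1000 µM and 59.3% (57.2 to 61.4) in the single-dose list, while the single-dose list had 87.5% (86.7 to 88.3) in that at 1000 µM. For HA-Twi the pair gave 84.6% (83.0 to 86.1), for the Zld domain 66.7% (64.1 to 69.3) and for the Grh domain 75.8% (74.8 to 76.8). The 52.7% of Zld DMSO regions called with taz is close to the lowest repeat, which involves the same DMSO list, and the values for Grh and HA-Twi lie inside the range of repeats.

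**Figure D4:**
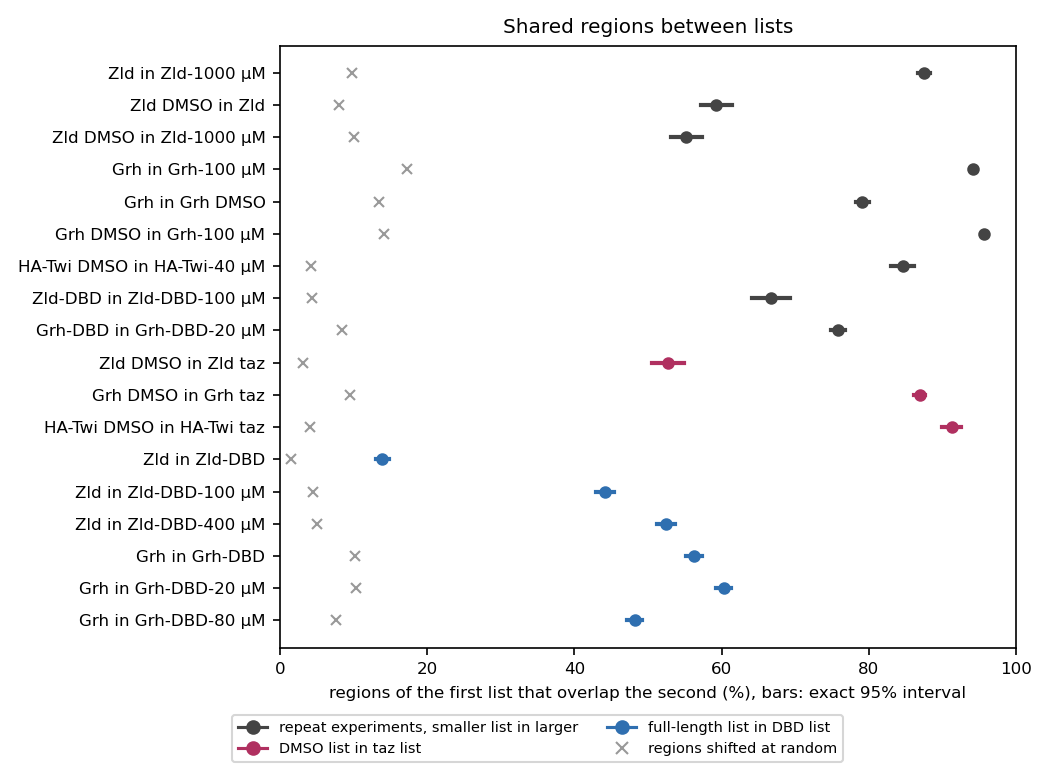
Share of the regions of a list that overlap a second list (horizontal axis, percent) for repeat experiments (grey), DMSO in taz (red) and full length in DNA-binding domain (blue); bars are exact 95% intervals and crosses the mean of random shifts. Repeat pairs lie between 55.2% and 95.7%, and the full-length Zld list reaches 13.9% in the single-dose list of its domain.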

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

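Of the tests in this part, those of mixed libraries and of regions missed with DMSO were set out before their result was seen; all others were chosen only after the result was seen.

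The region over zld that had nearly the same edges in all full-length Zld lists was also called in 4 HA-Twi dose lists, precipitated with anti-HA, where it was the strongest region at 0 (fold 11.7), 10 (17.8) and 40 µM (10.6). Binding of Twi over this whole extent is argued against by its presence in 0 of the 3 other lists of Twi lines, although the Twi list held a region of 984 bp inside it (fold 1.97), so that binding in that part stays open; signal of the anti-HA antibody alone is argued against by 0 wild-type anti-HA lists with it. Mixing in of finished anti-Zld libraries at a level that would bring their strong sites is argued against by a difference of -5 points. The test took the 100 strongest Zld regions at 1000 µM outside zld, the wild-type and the uninduced list. Of these, 8 were called in HA-Twi at 10 µM and 13 with HA-Twi and DMSO. Chromatin of the Zld line mixed in before precipitation stays open. The labels name no HA tag on Zld, so anti-HA would not bring its sites. DNA of a zld expression construct in these cells or libraries remains a candidate explanation, since in all 4 the edges lay within 39 bp of the median edges of the full-length Zld lists. However, a region of the list labelled wild-type anti-Grh, whose label is in doubt, covered 97.5% of the same extent with an edge 1382 bp away, which construct DNA in these cells would not bring if the label is right; a small admixture that brings only construct DNA stays open, and no further biological explanation was tested.

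The deposited lists held more regions with taz than with DMSO for HA-Twi and Zld, and outside the wild-type and uninduced lists the ratios went apart, 1.91 for HA-Twi and 0.868 for Zld; the difference between the factors was not tested. A deeper pileup in the taz calls is argued against by a recovered background per kb of 0.627 (HA-Twi) and 0.585 (Zld) times that with DMSO, although the taz pileups carry an unknown scaling and the depth of the libraries stays open. The authors' filter remains a candidate explanation for both, since the highest peak number with taz was 0.67 (Zld) and 1.04 (HA-Twi) times that with DMSO, and whether the filter kept more because the taz libraries resembled each other more is not known. For Zld the excess also lay among regions seen without induced factor (ratio 0.868 outside them). For HA-Twi that account is argued against by the ratio of 1.91. Of 1849 HA-Twi taz-only regions, 30.4% (28.4 to 32.6) were called at 40 µM without taz, below the 50% set in advance. This cannot decide whether the DMSO list missed regions by chance, because repeats do not reach that bar either. Of the 40 µM regions 49.0% were called in the DMSO list, its repeat. The HA-Twi taz-only regions were also weaker, with a median fold of 2.84 against 3.73 for taz regions shared with DMSO. The 40 µM list was filtered too (55.5% of numbers kept), so loss to the filter is not excluded. Variation between experiments and an effect of taz, each with 1 list per group, stay open.

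Regions that were strong after induction were already called at 0 µM for Zld and Grh. For Zld, signal of the antibody in cells without a construct is argued against by the strongest 10% of the lowest induced dose, of which 68.9 points more regions were called at 0 µM than in the matched wild-type list, and 58.9 points more than in any of the 4 wild-type lists. For Grh the difference was 53 points against the matched list, whose label is in doubt, and -0.1 points against the 4 lists together, so that signal of wild-type cells stays open there, although 42.9% of the 345 such regions outside all 4 lists were called at 0 µM. Factor made without added copper and carry-over of induced material also stay open: the uninduced share of Grh regions outside wild type was 58.7 times higher in the strongest than in the weakest 10%, but this restates the pattern and decides nothing.

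The Zld domain had more regions at its higher than at its lower dose (ratio 1.24) and the Grh domain fewer (0.799), and outside the wild-type and uninduced lists 442 against 202 (Zld) and 3673 against 4825 (Grh). This opposite direction was not tested, the 2 repeats of the Zld domain differed by 3.37-fold, and its highest peak number before the filter was 9316 at the lower and 9163 at the higher dose.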

How the results depend on the processing

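Alternatives that used all 4 wild-type lists together, that removed uninduced regions or that thinned a list were chosen only after the data were seen. No paired analysis was possible because each list pools the 2 libraries of a group. For the same reason leaving out each replicate gave no value. The motif alternatives were not run, since no genome sequence was used. Of the alternatives that gave a value, 110 lay within the interval or ratio limit, 125 lay outside it and 3 crossed a ratio of 1; unless the setting itself removes regions or loosens a window, the cause was not tested. Thinning removed almost no regions (2142 of 2150 Zld DMSO regions stayed), so it tests little. Depth and the authors' filter limit every region number. Removal of wild-type or uninduced regions took them from both lists of a pair, which by itself can lower a share.

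With a reciprocal overlap of at least 50%, a stricter rule by construction, the wild-type shares were 52.2% (Zld), 7.51% (Grh), 10.1% (Twi) and 12.2% (HA-Twi); the overlaps 43.3% (Zld in Grh), 55.5% (Zld in Twi) and 52.2% (Grh in Twi); the lowest doses called at the highest 69.4% (Zld), 64.4% (Grh) and 60.2% (HA-Twi); full length with the domain 10.1% (Zld) and 36.0% (Grh); and DMSO called with taz 40.0% (Zld), 81.0% (Grh) and 82.8% (HA-Twi).

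With a −log10 q of at least 10 in every list the wild-type shares were 65.9% (Zld), 15.8% (Grh), 18.4% (Twi) and 12.4% (HA-Twi), full length with the domain 12.2% (Zld) and 52.7% (Grh), and DMSO called with taz 41.1% (Zld), 66.7% (Grh) and 86.3% (HA-Twi). The number of Zld regions with taz over DMSO turned to 0.924 from 1.5.

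Among the 1000 regions of highest fold the wild-type shares were 46.6% (Zld), 19.7% (Grh), 7.6% (Twi) and 9.2% (HA-Twi); the overlaps 60.9% (Zld in Grh), 65.9% (Zld in Twi) and 80.0% (Grh in Twi); the lowest doses called at the highest 88.7% (Zld), 99.1% (Grh) and 98.9% (HA-Twi); full length with the domain 30.6% (Zld) and 84.8% (Grh); and DMSO called with taz 71.1% (Zld), 100.0% (Grh) and 99.3% (HA-Twi).

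With the repeat experiment's list the wild-type shares were 61.6% (Zld; 25.4% in its DMSO list), 13.1% (Grh) and 14.5% (HA-Twi, its DMSO list), the overlaps 80.2% (Zld in Twi) and 67.3% (Grh in Twi), and full length with the domain 40.7% (Zld) and 53.8% (Grh). With any of the 4 wild-type lists the background shares were 70.6% (Zld), 58.0% (Grh), 46.1% (Twi) and 54.2% (HA-Twi).

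Without wild-type regions the overlaps were 47.9% (Zld in Grh), 52.8% (Zld in Twi) and 51.2% (Grh in Twi), the lowest doses called at the highest 69.5% (Zld), 77.4% (Grh) and 87.7% (HA-Twi), and full-length Grh with the domain 53.6%. The Grh ratio of taz to DMSO stayed 1.0 at the printed precision while passing 1. Gene shares were, for Zld, 20.7% (epithelial), 36.7% (mesoderm), 21.7% (ribosomal), 33.3% (Polycomb), 16.7% (neural), 46.2% (germline) and 5.0% (copper and stress); for Grh 62.0% (ribosomal) and 38.5% (germline); for Twi 73.9% (ribosomal) and 73.3% (Polycomb); for HA-Twi 0.0% (germline).

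Without wild-type or uninduced regions the overlaps were 31.4% (Zld in Grh), 40.0% (Zld in Twi) and 51.2% (Grh in Twi), the lowest doses called at the highest 58.7% (Zld), 74.1% (Grh) and 87.2% (HA-Twi), the Zld dose ratio 2.01, full length with the domain 7.87% (Zld) and 48.4% (Grh), and DMSO called with taz 50.1% (Zld) and 85.1% (Grh). The Zld number with taz over DMSO turned to 0.868, while it stayed above 1 without wild-type regions alone (1.24). Gene shares were, for Zld, 13.8% (epithelial), 23.3% (mesoderm), 31.8% (blood cell), 7.61% (ribosomal), 30.0% (Polycomb), 11.1% (neural), 15.4% (germline), 0.0% (copper and stress) and 25.0% (factor loci); for Grh 50.0% (mesoderm), 60.9% (ribosomal), 83.3% (Polycomb), 38.5% (germline) and 50.0% (copper and stress); for HA-Twi 0.0% (germline) and 25.0% (factor loci).

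Without regions of any of the 4 wild-type lists the overlaps were 43.0% (Zld in Grh), 53.1% (Zld in Twi) and 44.8% (Grh in Twi), the lowest doses called at the highest 67.5% (Zld), 70.0% (Grh) and 81.2% (HA-Twi), the dose ratios 2.18 (Grh) and 3.81 (HA-Twi), full length with the domain 11.9% (Zld) and 36.1% (Grh), and DMSO called with taz 82.6% (Grh) and 92.6% (HA-Twi).

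With 1000 bp to a gene end, a wider window, 62.0% (Zld), 54.8% (Grh) and 47.6% (Twi) of summits lay near one. With the gene window of 500 bp around a gene end, a narrower one, the shares were 31.8% (blood cell), 60.0% (Polycomb) and 11.1% (neural) for Zld, 80.0% (Polycomb) for Grh, 62.1% (epithelial), 60.0% (mesoderm), 54.5% (blood cell), 80.0% (Polycomb), 69.2% (germline) and 60.0% (copper and stress) for Twi, and 0.0% (epithelial), 30.0% (mesoderm), 56.7% (Polycomb) and 0.0% (germline) for HA-Twi.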

Other observations

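The tests here were chosen after the data were seen. The wild-type anti-Grh list held regions of very high fold at genes of the fixed lists: Mef2 (fold 386), Antp (64.3), sog (63.9), NetA (57.5) and twi (24.3), against a list median of 3.53. The Mef2 region was the strongest of all 1946. Of its regions, 73.9% (71.9 to 75.9) lay in the Grh list of the induced line, with 33.0% of its strongest 10% and 37.6% of its weakest. It also held a region of 6307 bp over zld (fold 14.3), which reached 1382 bp beyond the region of the Zld lists.

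Merged regions found in no wild-type list numbered 12850, of which 22.4% lay near a gene end, against 51.9% of the 2422 found in 1 wild-type list and 46.1% of the 629 found in all 4. Of the 18718 merged regions, 4595 stood in 1 list only and 3744 in at least 16. The region of 1345 bp at grh that all 7 full-length Grh lists shared was also called in the HA-Twi list at 40 µM (edges within 26 bp, fold 2.9), in the Zld list at 1500 µM (54 bp, fold 5.57) and in wild type with anti-HA (105 bp, fold 2.77).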
